A study of Mus musculus with 6 samples.

How the data were processed

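RNA from the mouse myoblast cell line C2C12 was measured on 6 one-colour microarrays of the Arraystar mouse circRNA design, 3 for myoblasts and 3 for myotubes. Circular RNAs (circRNAs) are closed RNA rings, most of them formed when a downstream splice donor is joined to an upstream splice acceptor. Per the labels, total RNA was taken and labelled with Cy3, and the study describes 3 independent experiments per group. Whether linear RNA was removed before labelling is not given in the sources used here. Groups and replicate numbers were taken from the sample titles and the stated differentiation status.

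Each array came as a scanner table made with Feature Extraction 11.0.1.1, per the file headers. Per the file headers, the processed signal is an intensity on a linear scale, after the software's background subtraction and spatial detrending, and it was not scaled between arrays. The deposited spot and background columns are also intensities, in the scanner's raw units. The multiplicative detrending fit recorded in the header was 0 on the array of myotube 2 and 0.0306 on that of myotube 3, which shared a slide row. It lay between 0.0864 and 0.0987 on the arrays of the other row, the myoblast arrays and myotube 1. The deposited value table of the series held log2 values for 11128 circRNA probes, with array medians from 5.57 to 5.59 and a lowest value of 4.03. How the authors made those deposited log2 values is not given in the sources used here. Within each array their order followed the raw median intensity, with Spearman correlations from 0.996 to 0.999 across probes, against at most 0.975 with another array. The scale was therefore taken as log2 with each column matched to its array, no centring per probe was seen, and the step that made the array distributions alike stays unknown.

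The design held 14236 circRNA probes with 1 spot each, 50 gene probes with 10 spots each, 14 circRNA control probes, 15 custom probes and 15 negative probes. The files used here do not pair the circRNA probes with host genes, circRNA classes or circRNA names. The planned tests of host gene lists, of circRNAs sharing a host gene and of circRNA classes were for that reason not made, and circRNA probes are given by their identifier. The gene probes carry transcript accessions, and 44 of the 50 were given a symbol through a RefSeq gene table of assembly GRCm38.p6. The array headers name the older build mm9, so no coordinates are given.

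Spots with a non-uniformity or population outlier flag were left out (34 to 72 spots an array), and no circRNA spot was saturated. Spots of one probe were averaged on the log2 scale. The main values were log2 of the processed signal minus each array's 75th percentile over all non-control probes, since over 50% of the circRNA probes were detected. All differences are relative to that percentile, and a common rise or fall of most circRNAs would not appear in them. A probe with several spots counted as above background when at least 50% of its spots did. Probes were tested where they were well above background on all 3 arrays of at least 1 group, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. circRNA probes and gene probes were fitted and adjusted separately. The fit had no block for the replicate number. Single values per array were compared by an exact permutation test, in which 3 arrays against 3 cannot give a p below 0.1.

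A probe that was not well above background on any array of a group had only a bound there. Its fold is given as at least the bright group's mean over the dim group's mean, where each dim array entered with the higher of the lowest signal among probes well above background and the probe's own signal. The number of arrays limits the precision of every value.

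The circRNA probes described singly were chosen by a rule fixed before the data were examined. It took the 2 called probes with the greatest rise and the 2 with the greatest fall, among those above background on at least 2 arrays of each group and with groups that did not overlap. It also took, per direction, the called probe with the greatest bound among those above background on all arrays of 1 group and on none of the other, whose identifiers are not printed. The gene probes were not foreseen in that rule. Gene probes past the threshold, those with an unadjusted p under 0.05 and members of the fixed lists were named, and Apoe, Olfr166 and Lhx1 were added, all after their values were seen. The 16 gene lists had been fixed for host genes and were looked up among the gene probes instead.

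The alternatives set before the data were examined were normexp background correction (offset 50), quantile normalization, both together, median scaling, the 75th percentile over probes above background on all arrays, no filter or a stricter filter on dim probes, a variance trend, array weights, the replicate number as a block, the deposited values, kept outlier flags, other thresholds, and each array left out in turn. The mean spot signal planned for normexp was not among the columns used here, and the median spot signal took its place. The slide row as a block, the first slide row alone, and the removal of block medians over the array were added after the data were seen, as was every result on gene probes. All 6 arrays lay on 1 slide with 1 scan time stamp, so slide and scan could not be blocks.

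The fit was tested on simulated data made from the 9325 circRNA probes with complete values. With 200 changed probes it called 6% of those changed 1.5-fold, 44% at 2-fold, 74% at 3-fold and 90% at 4-fold, and 5.31% of its calls were false. With 3000 changed probes it called 49.2% at 1.5-fold, 81.4% at 2-fold and 97.8% at 4-fold, with 3.59% false. The simulated noise was drawn for each probe on its own, around values already scaled. It held no shift shared by an array, a slide row or probes of like brightness. The false shares therefore do not give the error of the calls on the real arrays.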

Results

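C2C12 is a mouse line of muscle precursor cells that fuse into multinucleate myotubes when serum is lowered. Myoblasts were grown in 10% fetal bovine serum, and myotubes were obtained after a change to 2% horse serum. circRNAs were measured on 6 arrays, 3 from myoblasts and 3 from myotubes, to find which circRNAs differ between the states. Each array carried 14236 circRNA probes and 50 probes for genes.

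Every myotube array had more detected circRNA probes than every myoblast array. Probes well above background numbered 8710, 8897 and 8403 on the myoblast arrays and 9392, 10059 and 10408 on the myotube arrays. The means were 8670 ± 249 in myoblasts and 9953 ± 516 in myotubes (SD, n = 3 each; 2-sided exact permutation p = 0.1, the smallest this design allows). The 75th percentile of the processed signal of the circRNA probes, before scaling, was 33.2 ± 3.12 in myoblasts and 48.6 ± 9.60 in myotubes (SD, n = 3 each; exact permutation p = 0.1). Of the myotube arrays, myotube 1 stood at 37.6, close to the highest myoblast array at 36.4. The brightest 100 circRNA probes held 63.6% ± 2.86 of the circRNA signal in myotubes and 71.6% ± 1.45 in myoblasts (SD, n = 3 each; exact permutation p = 0.1). Myotube 1 lay on the slide row of the myoblast arrays and myotubes 2 and 3 on the other row.

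**Figure D1:**
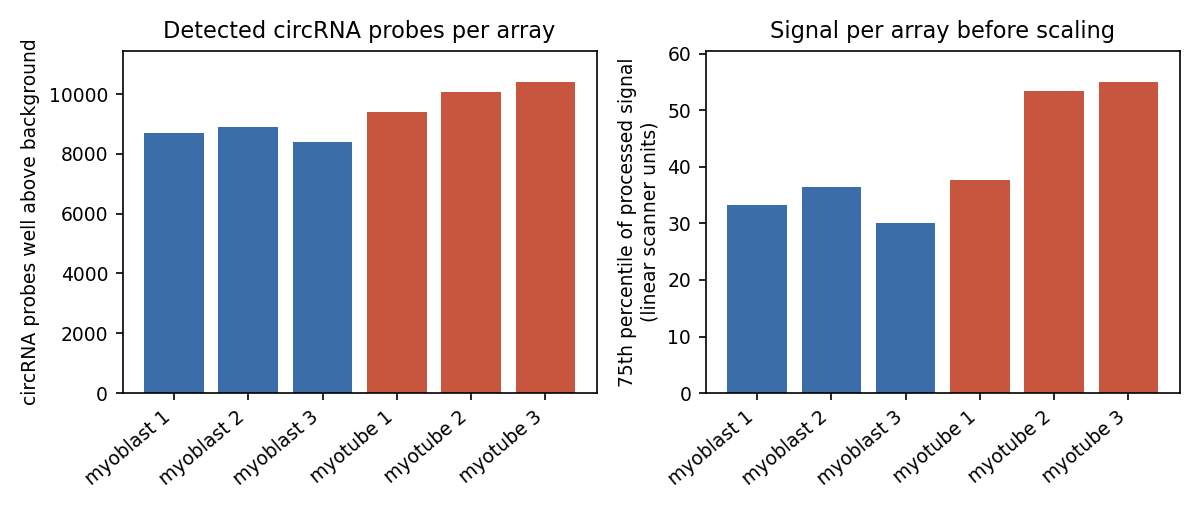
Bars show, for each of the 6 arrays (blue, myoblast; red, myotube), the number of circRNA probes well above background (left) and the 75th percentile of their processed signal in linear scanner units before scaling (right). The myotube arrays reach 9392 to 10408 detected probes, all above the myoblast arrays, and myotube 1 has a signal of 37.6 beside 36.4 on the highest myoblast array.

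circRNA profiles differed widely between myoblasts and myotubes. Of 9348 circRNA probes tested, 3188 (34.1%) differed past the threshold in limma, 1782 of them higher and 1406 lower in myotubes. These directions are relative to each array's 75th percentile, which was higher on the myotube arrays. A small difference called lower therefore need not be a fall in signal. The greatest measured rise was that of ASCRP4004827, 52.8-fold, from a processed signal of 8.17 ± 0.377 to 627 ± 81.7 (SD, n = 3 each), a log2 difference of 5.72 (SE 0.18, adjusted p = 1.33e-06). ASCRP4001861 rose 28.2-fold (log2 difference 4.82, SE 0.30, adjusted p = 2.19e-05). The myoblast signals of these probes, 8.17 and 8.45, lay close to that of the negative probe MM9NEGATIVE017, 6.30 ± 1.02 (SD, n = 3). It was the 1 of 15 negative probes above background on all arrays. Both folds therefore rest on a dim myoblast signal, and the deposited values gave log2 differences of 4.53 and 3.62. The greatest measured fall was that of ASCRP4003188, which was 23.4-fold lower in myotubes, with a processed signal of 689 ± 13.4 in myoblasts and 43.6 ± 11.2 in myotubes (SD, n = 3 each; log2 difference -4.55, SE 0.16, adjusted p = 2.16e-06). ASCRP4001146 was 22.5-fold lower (log2 difference -4.49, SE 0.17, adjusted p = 3.22e-06). Normexp correction, whose offset of 50 shrinks differences of dim probes, made the differences of these 4 circRNA probes smaller. In the order named, the log2 differences were then 3.23, 2.44, -3.14 and -2.75.

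The differences were mostly moderate in size. With probes below background on a whole group set at their bound, 797 of the higher probes changed at least 2-fold, 140 at least 4-fold and 32 at least 8-fold. Among the lower probes these numbers were 574, 111 and 32. The median fold, bounds included, was 1.93 for the higher and 1.86 for the lower probes. The groups did not overlap for 4660 of the tested probes (49.9%). Chance gives 10% for a single probe on exchangeable arrays. The probes shared the same 6 arrays, and some were tested through detection in 1 group alone, so 10% is not the chance level of this share. Across circRNA probes, which are not independent replicates, correlations of log2 signal lay between 0.971 and 0.974 within myoblasts, between 0.965 and 0.980 within myotubes, and between 0.878 and 0.895 across the groups. The first principal component held 72.8% of the variance.

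The split of the calls by direction differed with the set of probes counted and with their brightness. Among called probes above background on at least 1 array of each group, 1402 were higher and 1358 lower in myotubes, and the probes below background in a whole group added 380 higher and 48 lower. With only probes above background on all 6 arrays tested, 1305 were higher and 1431 lower. These sets were defined by detection in each group, which a change itself alters, so they do not show the cause of the split. By brightness, 66.7% of the calls were higher among the 3116 dimmest tested probes. The share was 53.3% among the 3116 of middle brightness and 47.4% among the 3116 brightest. The test filter enters these shares too, since 9085 probes were well above background on all 3 myotube arrays and 7980 on all 3 myoblast arrays. Subtraction of 1 percentile per array also does not remove a shift that varies with brightness. The cause of the trend with brightness was not tested. The split also moved with the scaling. It was 55.9% higher under the 75th percentile, 46.6% (1512 of 3243) under median scaling, and 43.0% (1213 of 2819) after normexp correction, which moved the median of all tested probes by -0.10 on the log2 scale. With slide row as a block 1630 probes passed the threshold, and within the first row, which held the 3 myoblast arrays and myotube 1, 1117 did; in both fits myotube 1 alone gave the difference, and its spread was taken from the other arrays. Without myotube 3 the number was 2088.

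**Figure D2:**
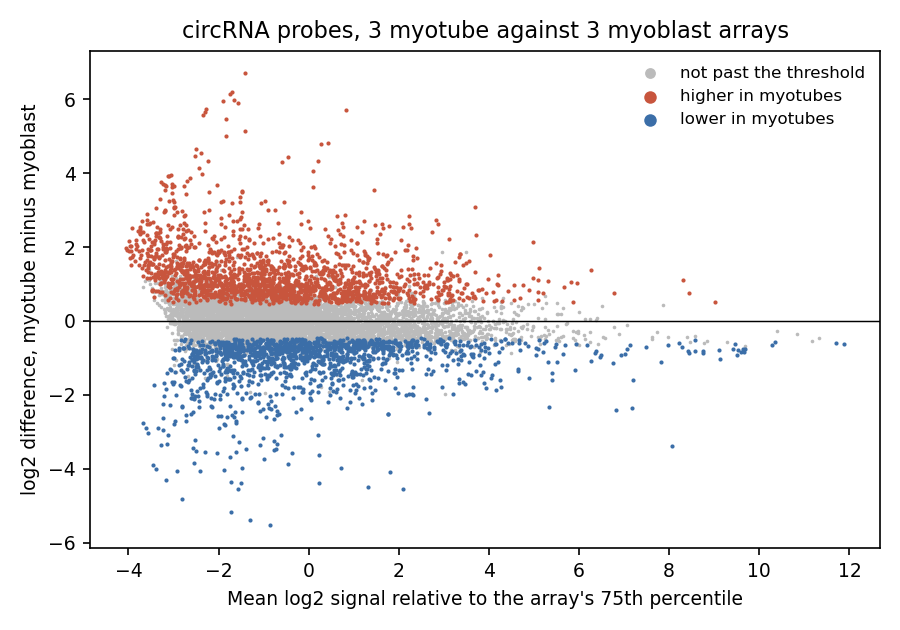
Each point is 1 of the tested circRNA probes, with its mean log2 signal relative to the array's 75th percentile on the x axis and the log2 difference, myotube minus myoblast, on the y axis; red and blue mark the 1782 higher and 1406 lower probes, and probes below background in a group are drawn at their fitted value. Called probes lie on both sides of 0, and of those above background on at least 1 array of each group 1402 are higher and 1358 lower.

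Some circRNA probes were well above background on the arrays of 1 group alone. Of the 14236 probes, 504 were well above background on all 3 myotube arrays and on no myoblast array, and 48 showed the reverse. Detection was read before scaling, and the brighter myotube arrays, with a 75th percentile of 48.6 against 33.2, would by themselves give more probes of the first kind. Past the threshold were 380 of the former and all 48 of the latter. Bounds were small for most of the gains, with a median of at least 1.59-fold and 119 probes at 2-fold or more. The 48 losses had a median bound of at least 3.28-fold, and 42 were at 2-fold or more. The greatest gain by this measure was at least 29.0-fold (adjusted p = 1.33e-06), for a probe with a processed signal of 1.25 ± 0.336 in myoblasts and 190 ± 53.8 in myotubes (SD, n = 3 each). The greatest loss was at least 18.4-fold (adjusted p = 2.31e-05), from 60.4 ± 8.33 to 2.77 ± 1.46. In both, none of the 3 arrays of the dim group was well above background, and after normexp correction their fitted log2 differences were 1.87 and -1.08.

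The 50 gene probes gave a view of named genes, and 10 of the 26 that could be tested differed past the threshold. Whether linear RNA had been removed is not given in the sources used here, so it is uncertain how far these values stand for messenger RNA. Hspb7, a small heat shock protein of heart and skeletal muscle, rose 5.95-fold (log2 difference 2.57, SE 0.33, adjusted p = 1.86e-04), from a processed signal of 11.5 ± 3.52 to 103 ± 51.3 (SD, n = 3 each). Gsta4, a glutathione S-transferase that acts on products of lipid peroxidation, was 4.09-fold lower in myotubes (log2 difference -2.03, SE 0.17, adjusted p = 2.79e-05). Actb, the cytoplasmic beta-actin often used as a reference gene, was 2.69-fold lower (log2 difference -1.43, SE 0.18, adjusted p = 1.86e-04). The direction of all these held under every scaling tried, with smaller log2 differences of 0.98, -0.60 and -0.97 after normexp correction. For all 10 called gene probes the groups did not overlap, as for 12 of the 26 tested.

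Also higher was the olfactory receptor probe Olfr1307 (log2 difference 2.18, SE 0.26, adjusted p = 1.86e-04), which was above background on 1 of the 3 myoblast arrays and had a log2 difference of 0.25 after normexp correction. Duox1, an oxidase that makes hydrogen peroxide, was above background on all 3 myotube arrays and no myoblast array, and was at least 1.51-fold higher (adjusted p = 2.55e-04). Its log2 difference was -0.06 after normexp correction with the 75th percentile. Anxa8, a calcium-dependent phospholipid-binding protein, had a log2 difference of 0.98 (SE 0.33, adjusted p = 0.0428), and the transcript ENSMUST00000062524 one of 0.93 (SE 0.21, adjusted p = 0.00613). Also lower were the transcript AK004226, with a log2 difference of -1.20 (SE 0.17, adjusted p = 2.58e-04), and H2-Q7, a class I histocompatibility gene, with -1.13 (SE 0.22, adjusted p = 0.0024). H2-Q7 and Olfr1307 belong to families with closely similar members, so which gene each probe read is uncertain.

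Only 3 of the 16 gene lists had a member among the gene probes. For cell cycle and DNA replication this was E2f1, a transcription factor of S-phase genes, which fell by 0.54 on the log2 scale (SE 0.19, adjusted p = 0.0452), a call counted both over all gene probes and when adjusted over the list alone. Its unscaled log2 signal differed by -0.0092, so the fall was relative to the rise of the percentile. For the actin cytoskeleton it was Actb, called both ways. For mitochondria and energy metabolism the glycolytic enzyme Gpi1 had a log2 difference of -0.29 (SE 0.23, adjusted p = 0.355) and Cpt1a, which brings fatty acids into mitochondria, one of 0.08 (SE 0.38, adjusted p = 0.883), so none of 2 was called, nor when adjusted over the list alone. The lists for sarcomere, calcium handling, dystrophin complex, myogenic regulators, extracellular matrix, RNA binding, chromatin, ubiquitin ligases, circRNA host genes, neuron, immune, fat and bone, and liver and epithelial genes had no member there.

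The calls of E2f1 and Anxa8 were the least secure. E2f1 passed the threshold in 6 of 19 alternatives and had a log2 difference of -0.25 with slide row as a block (adjusted p = 0.485), and Anxa8 passed it in 10 of 19. With that block H2-Q7 (log2 difference -1.05, adjusted p = 0.0510) and ENSMUST00000062524 (log2 difference 0.96, adjusted p = 0.0559) also missed the threshold at differences of about the same size, and the other 7 of the 10 passed it. Within the first row both passed it (adjusted p = 0.0333 and 0.0240). ENSMUST00000062524 also missed it after normexp correction, with a log2 difference of 0.11 (adjusted p = 0.278), as did Anxa8, with 0.11 (adjusted p = 0.439). Pex11a, a protein of peroxisome division, with a log2 difference of -0.50 (SE 0.18, adjusted p = 0.0562), and Lhfp, with -0.53 (SE 0.23, adjusted p = 0.0993), did not pass it.

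**Figure D3:**
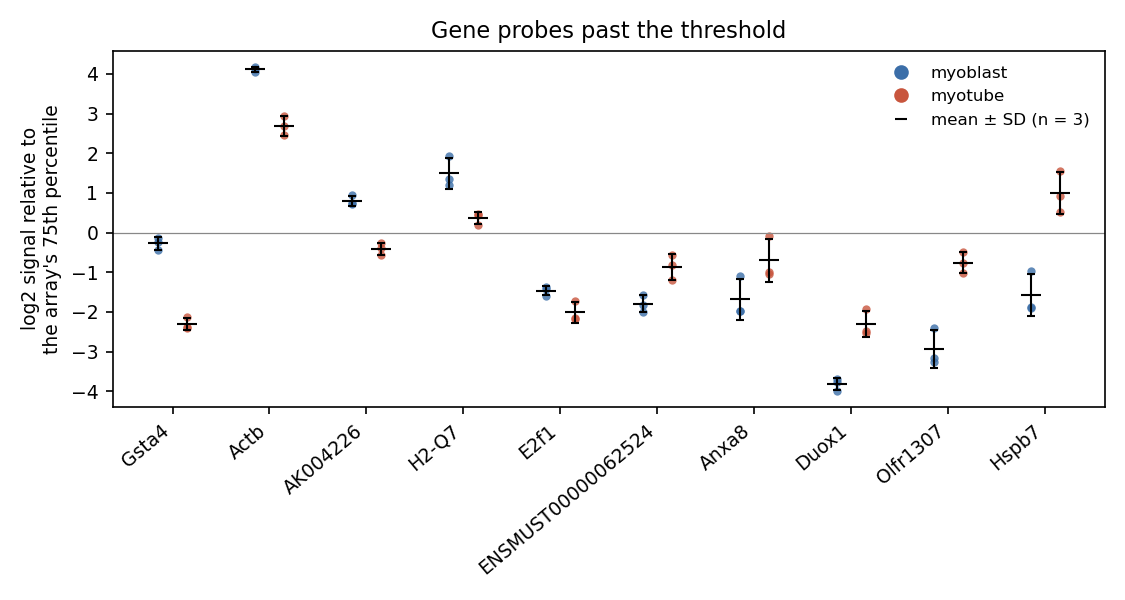
Points are single arrays (blue, myoblast; red, myotube) for the 10 gene probes past the threshold, with log2 signal relative to the array's 75th percentile on the y axis and bars for mean ± SD (n = 3). The groups do not overlap for any of the 10, and Hspb7 and Gsta4 lie farthest apart in opposite directions with log2 differences of 2.57 and -2.03; the Duox1 points of myoblasts lie below background.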

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

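The tests of overall gain, of slide row, of the splits for gene probes and of the removal of block medians were chosen after the results they bear on had been seen. Probes outside the comparisons of circRNA and gene probes also gave signal. Of the 14 circRNA control probes, all were above background on all arrays, and 4 were higher and 2 lower in myotubes past the threshold of limma. Of the 15 custom probes, 11 were above background on all arrays and 3 were lower in myotubes. What the control and custom probes target is not given in the sources used here. The negative probe MM9NEGATIVE016 had a fitted log2 difference of 0.97, where the other 14 negative probes lay between -0.60 and -0.22. The percentile was higher on the myotube arrays, so a probe of unchanged signal gets a negative difference. MM9NEGATIVE002, for example, had -0.52 with a processed signal of 1.006 ± 0.0049 in myoblasts and 1.012 ± 0.0037 in myotubes (SD, n = 3 each). MM9NEGATIVE016 was not well above background on any array, with a processed signal of 1.38 ± 0.128 in myoblasts and 3.95 ± 0.616 in myotubes (SD, n = 3 each), so the difference gives no fold.

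The number of called circRNA probes was 3188 for the real groups and 0 in each of the other splits of the 6 arrays with limma, where 67 to 505 probes had an unadjusted p under 0.05 against 4340 for the real groups. For gene probes the numbers were 10 and 0. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The other splits also put arrays of both states in each group, so a difference between states widens their spread. Their 0 calls therefore do not show what arrays without any difference would give. Fold changes of neighbouring spots correlated at 0.0338 across spots, just outside the range of -0.029 to 0.025 that held 95% of 1000 shuffles, so a slight spatial trend may be present. Removal of block medians over the array brought that correlation to 0.0199 and left 3198 called probes, 2948 of them among the 3188, which argues against such a trend as the source of the calls. Against slide row as the source of the calls, myotube 1 minus a myoblast array of its own row followed the differences of the second row's myotube arrays from the other myoblast arrays with slopes of 0.739 to 0.871, where myoblast arrays among themselves gave -0.0382 to 0.0731. A smaller part of slide row, and the change of state that the design names, stay open.

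Raw signal was higher on the myotube arrays, with a 75th percentile of 48.6 ± 9.60 against 33.2 ± 3.12 (SD, n = 3 each). A single gain for every probe on an array would shift gene probes as much as circRNA probes of like brightness. The median difference between them was -0.16 on the log2 scale over 20 gene probes (95% bootstrap interval -0.48 to -0.10). Single differences went both ways, from -2.05 to 2.58, so this comparison decides nothing. A gain alone would leave the share of the brightest 100 circRNA probes unchanged. That share was 71.6% ± 1.45 in myoblasts and 63.6% ± 2.86 in myotubes (SD, n = 3 each), which argues against a gain alone. Myotube 1, on the row of the myoblast arrays, had 66.9%, where their lowest was 69.9%. The share of the brightest 10 did not separate the groups, at 34.7% ± 0.514 and 31.6% ± 2.80 (SD, n = 3 each, exact permutation p = 0.3), with myotube 1 at 34.8%. The argument therefore rests on the share of the brightest 100. A common gain besides changes of single probes stays open. Slide row cannot be told apart from the group here, since myotube 1, the only myotube array beside the myoblast arrays, stood at 37.6, above their range of 30.1 to 36.4 but nearer to it than to the other myotube arrays. A greater amount of circRNA in myotubes is a biological explanation that was not tested.

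Myotube 1 had the fewest detected circRNA probes of the myotube arrays, at 9392. A candidate explanation is a smaller shift along the same differences between the groups. Its slope on the group difference was -0.0716 against myotube 2 and -0.0878 against myotube 3, where the myoblast arrays among themselves gave -0.0382 to 0.0731. The sizes are close to those among the myoblast arrays, so this cannot be told apart from the spread between arrays, and slide row would separate the same arrays.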

How the results depend on the processing

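The slide row and spatial settings, and every result on gene probes, were added after the data were seen. Called circRNA probes stayed within 1.5 times of 3188 under every scaling, filter and variance setting (2581 to 3899). The probes moved more than the count. Normexp called 2129 of the 3188 again (66.8%) and gave the same sign for 86.9% of all 3188. Normexp with quantile normalization called 2290 of the 3188 again (71.8%). The number was 2088 without myotube 3 and 3117 without myotube 1, the ends of the range with 1 array left out. It fell to 1630 with slide row as a block and 1117 within the first row; set alone against the myoblast arrays in the same way, myotube 2 gave 1284 and myotube 3 gave 1289, so a single myotube array gave fewer calls whichever it was. Stricter thresholds gave 1587 (fitted fold of at least 2), 1661 (adjusted p under 0.01) and 881 (treat at 1.5-fold).

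The share of higher probes, 55.9%, turned below 50% with normexp (43.0%), normexp and quantile normalization (48.9%), median scaling (46.6%) and probes above background on all arrays (47.7%); the cause was not tested. It was 52.8% with quantile normalization, 58.2% with the percentile over probes above background, 59.4% with no filter, 53.7% with a variance trend and also 53.7% with array weights, 51.4% with the deposited values and 56.0% to 59.4% with 1 array left out. The deposited values called 3058 probes, 2585 shared with the 3188 in the same direction and 0 in the opposite one, with smaller folds (slope 0.538). Of the 3058, 600 had a fitted fold of at least 2, against 1587 in the main fit. The deposited values hold no gene probes.

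With the replicate number as a block, 2828 circRNA probes were called, 58.9% of them higher. Same-numbered arrays did not deviate together (correlations -0.019, 0.018 and -0.088 across probes), and no array correlated best with its own number.

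All 124 alternative values of the circRNA probes described singly kept direction and call, though normexp, which adds an offset of 50, shrank them. These probes had been picked for the greatest differences, so this says little about the other calls. Of the gene probes, Gsta4, Actb, AK004226, Hspb7 and Olfr1307 also kept direction and call in every alternative. The difference of Duox1 turned to -0.0586 with normexp, and that of Gpi1 to 0.0228 in both slide row settings. Cpt1a, not called anywhere, turned to -0.17 (normexp), -0.10 (quantile), -0.0096 (both) and -0.0110 (median scaling), and with 1 array left out lay between -0.29 and 0.39. Lhx1, not called anywhere either, turned to -0.10 (normexp), -0.0029 (normexp and quantile), -0.0082 (median scaling) and -0.0203 (both slide row settings). Pex11a passed the threshold in 5 of 19 alternatives and Lhfp in 2. Without 1 array each, E2f1 was not called in 5 of 6 fits and Anxa8 in 3. Signal over background limits the folds of the 380 higher and 48 lower probes below background in a whole group. Slide or scan as a block, host gene lists, shared host genes and circRNA classes were not run.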

Other observations

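The test of probe identifiers was set before its result was seen. Some probes for genes best known from other tissues were above background in both states. The olfactory receptor probe Olfr166 had a processed signal of 50.2 ± 2.14 in myoblasts and 65.8 ± 16.5 in myotubes (SD, n = 3 each), with a log2 difference of -0.17 (SE 0.17, adjusted p = 0.481). Apoe, which carries lipids, gave 165 ± 4.85 and 206 ± 25.9, with a log2 difference of -0.22 (SE 0.16, adjusted p = 0.345). Both were above background on all 6 arrays. Lhx1, a homeobox transcription factor, was as well, with a log2 difference of 0.08 (SE 0.16, adjusted p = 0.699). As for Olfr1307, which gene the Olfr166 probe read is uncertain.

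Of the 24 gene probes that were not tested, most lay near the floor of the scale. Ppara, a nuclear receptor of fatty acid metabolism, was above background on 2 of the 6 arrays, and Mbp, a myelin protein, on 0. The negative probe MM9NEGATIVE017 was above background on all 6 arrays, at 6.30 ± 1.02 in myoblasts and 7.57 ± 0.875 in myotubes (SD, n = 3 each). Detection alone therefore does not show that a gene was expressed.

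One hypothesis was that circRNA probes with consecutive identifiers come from related circRNAs and move together. Over 6233 consecutive pairs of tested probes the correlation of log2 differences was 0.0096, inside the range of -0.025 to 0.024 that held 95% of 1000 shuffles of the identifiers. The identifiers thus gave no hint of which probes belong together.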
